A study of Homo sapiens with 6 samples.

How the data were processed

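Total RNA of immature dendritic cells grown from MUTZ3 or MUTZ3-shMRP4 cells was labelled, per the labels' protocols, as biotin cDNA from 10 µg of RNA, after 7 days in medium with 20% FCS, 100 ng/ml GM-CSF, 10 ng/ml IL4 and 2.5 ng/ml TNFalpha. Groups and gains were taken from the sample titles. Per the file headers, the scanner files hold the mean and median intensity of each spot and of its local background, from automatic segmentation of 1 image per scan, not background-subtracted. The quantification software and its version are not given in the sources used here. The authors' deposited value table holds intensity for 36 of the 44 gene probes, in whole numbers, and leaves out 8, called reference genes here. Its normalization is not given in the sources used here. Set against the median of the spots minus background, its slope was 0.96 to 1.00 for the MUTZ3 columns and 1.07 to 1.11 for the shMRP4 columns. ABCG1 was left out of this for MUTZ3 at gain 50. The values are thus linear and run in the same direction. More than the local background was subtracted, as the intercepts of that fit were −141 (MUTZ3) and −179 (shMRP4) at gain 100. These come from a fit on spot medians and are not the amount subtracted. For MUTZ3 at gain 100, ABCA1 was listed at 3296 and ABCA6 at 22238, against mean net intensities of 3579 and 22521. Such a subtraction widens the ratios of dim probes. What the shMRP4 columns were scaled to stays unknown. The column medians were 3193, 265 and 22 for MUTZ3 and 2912, 251.5 and 19 for shMRP4 at gains 100, 70 and 50.

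Mean foreground and mean background of each scan were corrected with normexp at an offset of 50 (limma 3.58.1 in R 4.3.3), fitted on all spots, and log2 values of the 3 spots of a probe were averaged. Control spots were then left out. A gene was usable at a gain where, on both arrays, its mean foreground lay above the mean + 2 SD of the negative-control spots and no more than 50% of its spots had a median at the scanner limit of 65535. Each scan was centred on the median of the genes usable on both arrays at that gain (32, 34 and 36 genes at gains 100, 70 and 50), and a gene's difference was the mean over its usable gains of shMRP4 minus MUTZ3. The error over spots combines the spot variances of both arrays, averaged over gains. An offset of 50 shrinks differences of dim genes, most of all at gain 50.

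The design, the alternatives and the gene lists were fixed before the data were examined. A few steps departed from that plan or were settled later. Of 66 negative-control spots, 3 on the MUTZ3 array were bright, which put the limit at gain 100 at 17600 and, with the limits of all 3 gains set that way, left 11 usable genes. The main limit therefore leaves out negative controls over 3 scaled median absolute deviations from their median (58 of 66 spots used, limit 2404), and the limit as planned is kept as an alternative. Scans were to be centred on housekeeping genes named as such, and as the files name none in that way the planned fallback, all usable genes, became the main setting. Centring on all usable genes, also planned as a variation, is then the main setting itself. Centring on the internal standards was first run with a separate median on each array, and was changed, after its result was seen, to the median of the probes' own differences, because the 12 standards lie far apart in level. Both versions are given, and likewise for the 8 reference genes. The spread that decides whether a value moved, the larger of the SD over gains and the SD over spot positions, was defined after the data were seen. In all, 16 alternatives and a lower size threshold were planned, and 8 alternatives were added after seeing the data. Among the 16, centring on the standards stands in its changed version. The 8 include its first-run version and the limit that was planned as the main one.

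With 1 RNA sample per group no test across genes was made and no p-value is given for a gene. Genes were counted as higher or lower by size alone, at least 2-fold and of the same sign at every usable gain. A gene above background on 1 array only would count where its bound, against the lowest signal well above background on the other array, reached 2-fold. Lists with at least 3 usable members were summarised by their median, set among 10000 random lists of the same size drawn from the compared probes in 3 bins of mean level. With an odd number of members that median is 1 member's own value. Genes named are ABCC4, the 10 largest differences in each direction with the same sign at every usable gain, genes above background on 1 array only, and members of the fixed lists. The lists for multidrug efflux (2 usable members, ABCC1 and ABCC3), erythroid genes, epithelium, retina, hepatocyte, subfamily E and subfamily G had fewer than 3 usable members and were given by gene only. Lists for beta cell or muscle, lung and keratinocyte genes had 0 members with a probe of their own. Results for 2 of the compared probes, and the list medians they set, are not reported here.

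Of the 44 gene probes, 34 were matched to 1 current symbol through the RefSeq gene table of GRCh38.p14, 4 stand for several genes and 6 kept the array's name. Matches through older symbols were accepted for ABC names, GAPD and HPRT only. The table also gave which genes lie within 1 Mb of each other. Probe positions are not analysed here.

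The steps were tested on simulated data, with known differences in 12 of 39 genes in each of 100 simulations of shMRP4 against MUTZ3. A true log2 difference of −2 came out at −1.27 (offset 0, −1.65) and was called in 80.5% of the 251 cases that stayed usable. One of −1 came out at −0.73 and was called in 19.9% of 276 usable cases. Each size of rise had 300 usable cases. Simulated genes left unusable do not enter these rates, so drops were missed more often than the rates show. A true 1 came out at 0.66 and was called in 6.33%, and a true 2 came out at 1.48 and was called in 95.0%. There were 0.07 false calls per simulation. Differences near 2-fold were thus mostly missed and larger ones shrunk. The simulated spots had 1 small scatter for all probes and no outlying spots, and as many genes rose as fell. On the real MUTZ3 array the spot SD of ABCC10 at gain 100 was 1.08 on the log2 scale. The rates therefore hold for the simulated setting, and the real arrays can hold more false calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.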

Results

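RNA from immature dendritic cells was profiled on a low-density array of ATP-binding cassette (ABC) transporter genes. The cells were grown from MUTZ3, an established human leukaemia line that can be cultured into dendritic cells, or from MUTZ3-shMRP4, the line that carries a short hairpin RNA against MRP4, the product of ABCC4. Both were cultured for 7 days with GM-CSF, IL4 and TNFalpha. Each group had 1 RNA sample on 1 array, read at 3 scanner gains (100, 70 and 50), and the 3 readings of an array were counted as 1 replicate. Each array held 270 spots, 3 for each of 90 probes, of which 44 were for human genes (34 for ABC transporters and 10 for other genes). On the MUTZ3 array 41, 36 and 37 gene probes lay above background at gains 100, 70 and 50, and on the shMRP4 array 39, 35 and 37. Saturation affected 6 gene probes on each array at gain 100, and 1 on the MUTZ3 array at gain 70. With both arrays needed at the same gain, 39 of the 44 probes could be compared. The number of arrays limits the precision: no difference below has a replicate check and none was tested, and spreads over spots or gains are technical.

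The comparison of shMRP4 with MUTZ3 cells asked how the transporter genes differed when MRP4, an exporter of prostaglandins, leukotrienes and cyclic nucleotides, was targeted. The labels name no control hairpin or vector for the MUTZ3 cells. Targeting of MRP4 and the presence of a hairpin therefore cannot be told apart. ABCC4 itself was lower in shMRP4 cells by 2.14-fold, a log2 difference of −1.10 with a standard error over spots of 0.19. At gain 100 its net intensity was 5572 ± 239 in MUTZ3 and 1277 ± 361 in shMRP4 cells (SD, n = 3 spots). The log2 difference was −1.75 at gain 100, −1.04 at gain 70 and −0.51 at gain 50, so the direction was shared and the size on this scale was not. Net intensity in MUTZ3 and shMRP4 cells was 480 and 164 at gain 70, and 42.8 and 7.76 at gain 50. The values at gain 50 lie below the offset of 50, which shrinks the log2 difference there. At gain 70 the net intensities themselves differed by a smaller factor than at gain 100, so the offset is only part of that gap. The shMRP4 spots lay far apart at gain 70, at 164 ± 91.7 (SD, n = 3 spots). In the authors' deposited table ABCC4 was listed at 5289 against 1067 at gain 100, 450 against 135 at gain 70 and 40 against 6 at gain 50. It was further from 0 with plain background subtraction (−1.83), with offset 0 (−1.72, or −1.71 without outlying spots too), with separate medians of the standards (−1.71), at the highest usable gain only (−1.75) and in the deposited table (−2.06 centred, −2.26 with its own scaling). It stayed below 2-fold without background subtraction (−0.62) and without the gain 100 scans (−0.77). The same held when centred on the usable ones of the 8 reference genes, the human probes left out of the deposited table. ABCC4 was then −0.54 by the probes' own differences and −0.73 by separate medians. At gain 100 only CYC, HPRT1 and PLA2 entered that centring, as the other reference probes were saturated.

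**Figure D1:**
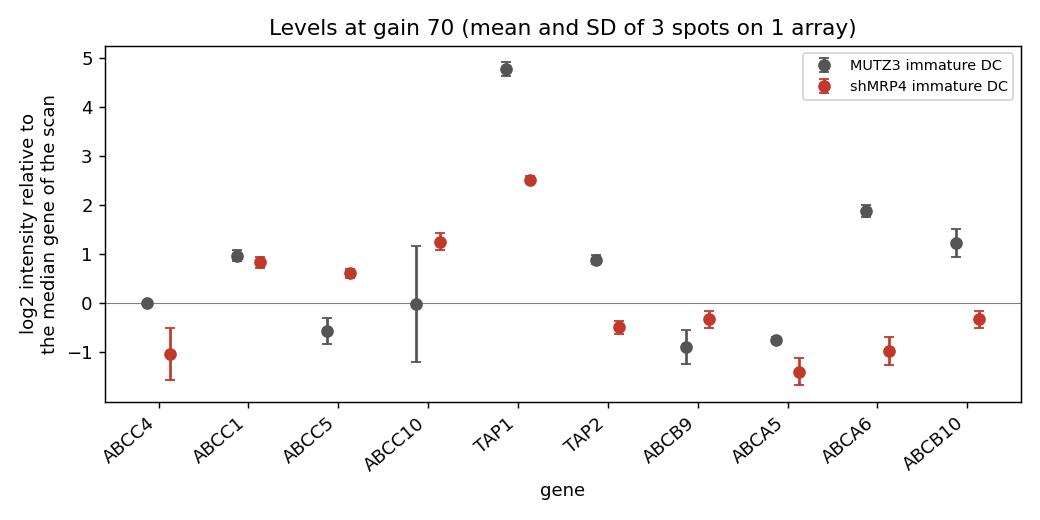
Log2 intensity at gain 70 relative to the median gene of the scan (vertical axis) for 10 genes (horizontal axis) in MUTZ3 (grey) and shMRP4 (red) immature dendritic cells; points are means and bars are SDs of 3 spots on 1 array. At this gain ABCC4 was −1.04, TAP1 −2.25, TAP2 −1.38 and ABCA6 −2.84 in shMRP4 minus MUTZ3, while ABCC5 was 1.17 and ABCC10 1.26 with a wide spread of the MUTZ3 spots.

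By the rule of at least 2-fold with 1 sign at every usable gain, 7 probes were lower and 2 were higher in shMRP4 cells. ABCA6, a subfamily A transporter tied to lipid handling in macrophages, was at −2.47 over 3 gains (5.54-fold lower, standard error over spots 0.16) and TAP1 at −2.21 over 2 gains (4.61-fold lower, 0.08). Their order turned at gain 50, with no background subtraction and with the limit over every negative control. The other lower probes were PLA2 at −1.70, ABCB10, a mitochondrial transporter tied to haem synthesis, at −1.36, TAP2 at −1.34, TUBU at −1.15 and ABCC4. The 2 higher probes were ABCC10 (MRP7), an exporter of lipophilic anions, at 1.06 with a standard error of 0.55, and ABCC5 (MRP5), an exporter of cyclic nucleotides, at 1.03 with 0.18. PLA2 and TUBU are the array's own names for 2 of its reference probes, and no current symbol was matched to them.

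The balance of higher to lower probes depended on the scaling between arrays. Against 2 higher and 7 lower, quantile normalization gave 4 and 6, and centring on the internal standards, plant transcripts spotted as controls, gave 0 and 8, as did no scaling. Separate medians of the standards gave 0 and 15. Centring on those of the 8 reference genes usable at each gain gave 8 and 3, or 6 and 3 with separate medians. The authors' deposited table gave 4 and 6 after centring and 3 and 6 with its own scaling, over 31 probes. The median difference of all compared probes, 0.04 in the main setting, was −0.23 and −0.65 with the standards, −0.26 with no scaling, and 0.61 and 0.44 with the reference genes, so each difference is relative to that level. No probe among the 9 changed sign in any of the 24 alternatives that gave it a value. The 9 were picked for a difference of at least 2-fold, and no scaling moved the median of all compared probes by that much. Their kept signs are therefore little evidence of stability. ABCA6 and TAP1 stayed at least 2-fold lower in 24 of 24, ABCB10 and TAP2 in 21 of 23, PLA2 in 21 of 22, ABCC4 in 19 of 23 and TUBU in 16 of 22. The higher probes held less often, ABCC5 in 15 of 23 and ABCC10 in 13 of 23.

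**Figure D2:**
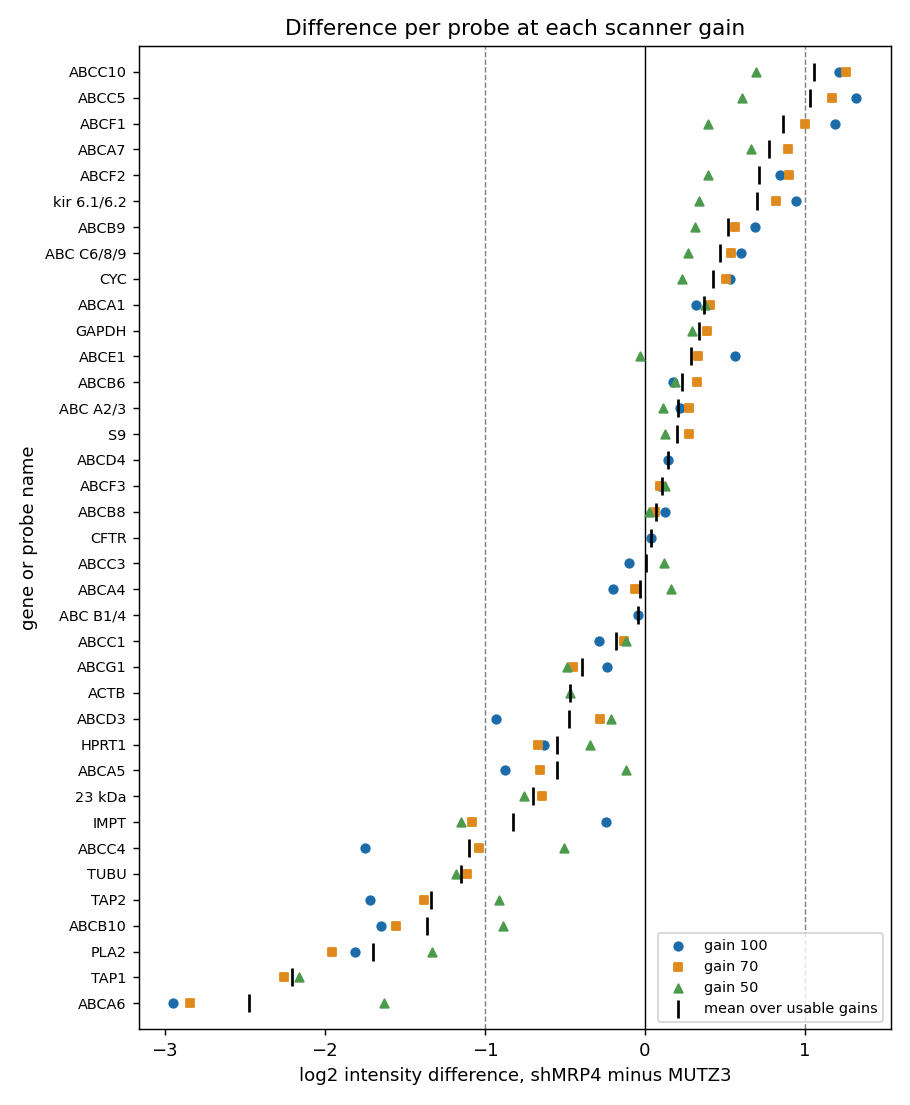
Log2 intensity difference, shMRP4 minus MUTZ3 (horizontal axis), for 37 of the 39 compared probes (vertical axis), at gain 100 (circles), 70 (squares) and 50 (triangles), with the mean over usable gains as a black tick and dashed lines at 2-fold. The 7 probes at least 2-fold lower run from ABCA6 at −2.47 to ABCC4 at −1.10, and ABCC5 (1.03) and ABCC10 (1.06) lie just past 2-fold on the other side.

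Of the peptide transporters, TAP1 and TAP2, which form the transporter that loads peptides for MHC class I, were both lower, and ABCB9, a lysosomal peptide transporter, was at 0.52 and turned to −0.091 with separate medians of the standards. The list's median of −1.34 is TAP2's own value, as the list has 3 members. It lay at percentile 1.1 of 10000 random lists of the same size and like level, drawn from the same 39 probes. The median stayed negative under every scaling, from −1.95 to −0.78, which is TAP2's own range. At gain 70 the net intensity of TAP1 was 15530 ± 1470 in MUTZ3 and 2512 ± 126 in shMRP4 cells, and that of TAP2 was 968 ± 67.6 and 255 ± 28.1 (SD, n = 3 spots).

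Among the exporters of eicosanoids, cyclic nucleotides and conjugates, 5 of 6 members could be compared. By the rule ABCC4 was lower and ABCC5 and ABCC10 were higher, though ABCC10 came to 0.73, under 2-fold, without outlying spots. ABCC1 (MRP1), tied to dendritic cell migration, was at −0.18 with a standard error over spots of 0.09. Its sign turned with the scaling, from −0.79 to 0.38. ABCC3 was at 0.01 and differed in sign between gains. The list's median of 0.01, at percentile 51.7, is ABCC3's own value and turned sign with the scaling, from −0.71 to 0.53. ABCC3 was dim, with net intensities of 4.47 in MUTZ3 and 3.75 in shMRP4 cells at gain 50. It was not usable at gain 70. With the background limit at 3 SD the list's median came to 0.44, so it says little about the exporters as a group. ABCC2 was above background on the MUTZ3 array and not well above background on the shMRP4 array, and its bound was below 1, so no fold is given. Its MUTZ3 spots lay far apart, with net intensities of 722 ± 544 at gain 100 and 109 ± 133 at gain 70 (SD, n = 3 spots). At gain 70, 1 of them was an outlying bright spot.

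Of the cholesterol and phospholipid transporters, ABCA7 was at 0.78 and ABCA1, which exports cholesterol to apolipoproteins, at 0.37 (from −0.24 to 0.93 over the scalings), with a list median of 0.37 at percentile 82.1. The median had the same range. ABCG1, a cholesterol exporter, was at −0.39 with a standard error over spots of 1.13, at 0.81 without outlying spots, and of a sign that turned with the scaling. Members without a membrane domain, which act in translation, had a median of 0.50 at percentile 92.6, with ABCF1 at 0.86, ABCF2 at 0.71, ABCE1 at 0.29 and ABCF3 at 0.10, of which ABCE1 and ABCF3 turned sign with the scaling. That median turned to −0.11 with separate medians of the standards and to −0.042 in the authors' deposited table with its own scaling. It came to 0.10 without outlying spots, where ABCF1 was at 0.02, ABCF2 at 0.36 and ABCE1 at −0.38. ABCE1 also differed in sign between gains, from −0.028 at gain 50 to 0.56 at gain 100.

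Of the mitochondrial transporters, ABCB10 was lower, while ABCB6 was at 0.23 and ABCB8 at 0.07, both with signs that turned with the scaling. In the peroxisomal and lysosomal D family ABCD3 was at −0.47 and ABCD4 at 0.14, and both turned sign with the scaling too. By subfamily the medians were −0.03 for A (mean −0.38, percentile 45.0) and 0.02 for C (mean 0.14, percentile 55.6), and both turned sign with the scaling. The C median lies between the values of ABCC3 and CFTR, which were both dim. For F the median was 0.71 (mean 0.56, percentile 92.6) and ran from 0.10 to 1.27 over the scalings. The F median came to 0.18 without outlying spots, to between 0.12 and 0.99 with 1 spot position left out, and to 0.0061 in the authors' deposited table with its own scaling.

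The 8 reference genes did not move as a block. TUBU and PLA2 were at least 2-fold lower, 23 kDa was at −0.70, HPRT1 at −0.55 and ACTB at −0.47, and S9 was at 0.20, GAPDH at 0.34 and CYC at 0.43. Their median of −0.51 lay at percentile 32.8 and ran from −0.76 to −0.03 over the scalings, under some of which HPRT1, S9 and CYC turned sign. Among members typical of other cell types, CFTR (epithelium) was at 0.04 and ABCA4 (retina) at −0.03, both with signs that turned with the scaling, and of the erythroid or progenitor genes ABCB10 was lower and ABCB6 at 0.23. Neither of the 2 hepatocyte or bile genes on the array, ABCB11 and ABCC2, could be compared, nor could ABCA8, ABCD2 and ABCG2.

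Other probes named by size were ABCA5, within 1 Mb of ABCA6, at −0.55, IMPT at −0.83 with a standard error of 1.27, the shared probe kir 6.1/6.2 at 0.70 and the shared probe ABC C6/8/9 at 0.47, which turned to −0.14 with separate medians of the standards. ABCA5 came to 0.01 when centred on the reference genes. IMPT came to 0.52 and ABCC10 to 0.73 without outlying spots. At gain 100, 13 spots of the MUTZ3 array and 6 of the shMRP4 array lay over 2-fold from the median of their probe's 3 spots, and 11 of the 13 stood in rows 12 to 15 and columns 3 to 6, a block of 16 spots outlined after the values were seen. Spots of ABCC10, ABCE1, ABCF1, ABCF2, ABCG1 and IMPT were among them.

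**Figure D3:**
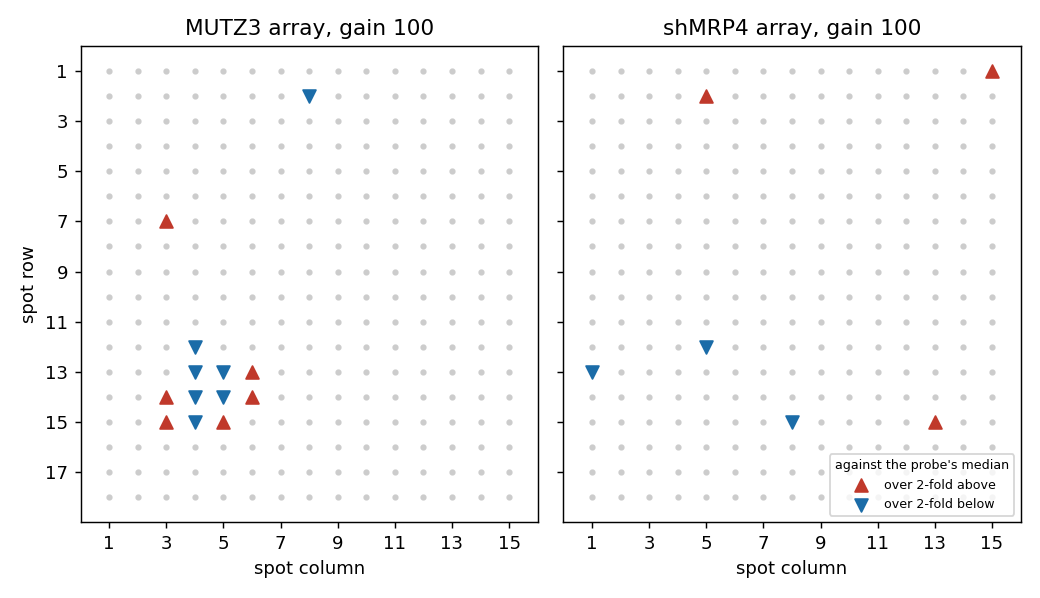
Spot row (vertical axis) against spot column (horizontal axis) for the 270 spots of the MUTZ3 array (left) and the shMRP4 array (right) at gain 100; red and blue triangles mark spots over 2-fold above and below the median of their probe's 3 spots. On the MUTZ3 array 11 of 13 marked spots lie in rows 12 to 15 and columns 3 to 6, and the 6 on the shMRP4 array are spread out.

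Across genes, which are not independent replicates, the differences at one gain followed those at another, with r from 0.89 to 0.97 and rho from 0.93 to 0.98. Deviations of single spots from their probe's mean were shared between gains on the MUTZ3 array (rho from 0.72 to 0.83 over 87 spots), and less so on the shMRP4 array (rho from 0.17 to 0.34). Between the arrays rho ran from −0.19 to −0.07. Each group lay on 1 array of its own, so array and group cannot be told apart.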

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

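All tests in this part were chosen only after the result was seen. On the MUTZ3 array 3 negative-control spots were over 2 times as bright as the median negative control at gain 100, against 0 on the shMRP4 array. They are not gene spots, but the normexp fit includes them, and the main background limit had to leave them out. The brightest read 45813, where the median was 2139.

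These 3 spots stood among the 13 outlying spots of that array, of which 11 lay in 1 block of 16 spots. Of the 13, 84.6% deviated the same way at gain 70, by a log2 difference over 0.5, which argues against a fault of 1 scan. The outlying spots lay closer together than randomly drawn spots (mean distance to the nearest other 1.78 against a median of 2.67, one-sided permutation p = 0.011), so a local defect of the array surface, such as debris or damage, is a candidate explanation. The design gives no biological explanation to test, since spots of 1 probe saw the same RNA. What stays open is the kind of defect, and whether it touches spots that do not stand out.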

How the results depend on the processing

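The alternatives for reference genes, outlying spots, the highest usable gain and the submitters' scaling were chosen after seeing the data. The limit over every negative control was the planned main limit, kept as an alternative after the main limit was changed. For the standards, separate medians were run first, and the probes' own differences were chosen after that result was seen. No called gene changed sign in any alternative, which their choice by size made likely. Of the values for ABCC4 and the list medians, 160 moved by less than their technical spread and 46 by more, and of those for other single genes 660 and 202. A wide spread hides moves. It was 1.11 for the members without a membrane domain (median 0.50) and 1.01 for subfamily F (0.71), and no value of either counted as moved. For ABCC4 it was 0.62, so −0.54 against −1.10 did not count either. The tally is therefore no measure of stability. Of the numbers of higher or lower genes, 29 stayed within 1.5 times the main number and 21 did not. The cause was not tested. No paired analysis was possible because each group had 1 RNA sample and no test was made. Signal over background limits the dim genes: ABCC4 was 42.8 above background at gain 50 in MUTZ3 and 7.76 in shMRP4 cells, below the offset of 50.

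ABCC4 was −1.83 with plain subtraction, −1.72 with offset 0, −1.75 at the highest usable gain only, and −2.06 (centred) or −2.26 (submitters' scaling) in the deposited table. It lay between −1.18 and −1.02 with 1 spot position left out.

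The number of higher genes, 2 in the main setting, was 4 with quantile normalization, 0 with the internal standards (also by separate medians), with no normalization, with no background subtraction, without gain 100 and without gain 70, 5 with plain subtraction, 1 with the median of spots and without outlying spots, 4 without outlying spots at offset 0, 4 in the deposited table after centring, 8 with the reference genes (6 by separate medians), 1 with the limit over every negative control, and 6 at 1.5-fold. It was 1 to 2 with 1 spot position left out. The number of lower genes, 7, was 3 with the reference genes in both versions, 2 with the limit over every negative control, where 11 genes were usable and only the reference gene list kept 3 or more members, and 15 with separate medians of the standards. It was 7 to 9 with 1 spot position left out.

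Peptide transport (−1.34) was −1.93 with plain subtraction, −1.84 with offset 0, −1.98 and −2.18 in the deposited table (centred, submitters' scaling), −0.78 and −0.97 with the reference genes (own differences, separate medians), −1.004 with no background subtraction, −1.70 without outlying spots at offset 0, −1.72 at the highest usable gain only and −1.95 with separate medians of the standards. Exporters (0.01) were 0.44 with the limit at 3 SD, 0.53 and 0.48 with the reference genes and −0.71 with separate medians of the standards. Cholesterol and phospholipid transport (0.37) was 0.74 with the median of spots, 0.76 in the centred deposited table, 0.93 and 0.73 with the reference genes, 0.81 without outlying spots, 1.03 at offset 0 as well, and −0.24 with separate medians of the standards. It lay between 0.29 and 0.82 with 1 spot position left out.

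Subfamily A (−0.03) was 0.53 with the reference genes and −0.65 with separate medians of the standards. Subfamily C (0.02) was −0.28 with no normalization, 0.33 with plain subtraction, 0.44 with the limit at 3 SD, 0.37 in the centred deposited table, 0.60 and 0.58 with the reference genes and −0.75 with separate medians of the standards. The reference genes (−0.51) were −0.026 with quantile normalization, −0.72 and −0.76 with the standards (own differences, separate medians), −0.76 with no normalization, −0.18 with no filter, −0.65 without gain 50, −0.025 and −0.17 when centred on themselves, −0.30 with the limit over every negative control and −0.37 without outlying spots at offset 0.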

Other observations

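The 4 tests on the lower probes and the test on neighbouring genes were chosen only after the results were seen. Without outlying spots, an alternative added after seeing the data, ABCG1 was higher in shMRP4 cells by 0.81, close to ABCA7 at 0.84 and above ABCA1 at 0.44. With an offset of 0 as well, ABCG1 came to 1.13, ABCA7 to 1.03 and ABCA1 to 0.65, so the 3 genes of cholesterol and phospholipid transport then shared a direction. In the authors' deposited table ABCG1 was 2711 in MUTZ3 and 5097 in shMRP4 cells at gain 100, 260 and 440 at gain 70, and 186 and 37 at gain 50. For MUTZ3 the ratio of gain 70 to gain 50 was 1.40 for ABCG1, where the median over 25 probes was 11.3 and the next lowest 7.04. The mean net intensity of its 3 MUTZ3 spots was 14492, 1793 and 189 at gains 100, 70 and 50, and its outlying spot read 534 at gain 50. The deposited 186 thus lies near the mean with that spot, while 2711 and 260 lie far below theirs. The turn of ABCG1 at gain 50 in that table goes with this spot.

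Besides ABCC4, 6 probes were at least 2-fold lower in shMRP4 cells, among them ABCA6, TAP1 and TAP2. A dimmer shMRP4 array would lower the internal standards by about as much, but without centring the 12 standards had a median of −0.025 (quartiles −0.071 and 0.066), against −1.42 for the smallest drop. A uniform loss of labelled cDNA would lower every gene, but without centring 11 of 39 genes lay above 0, among them ABCA7 at 0.50 and ABCC5 at 0.74, and the median of all 39 was −0.26. Centring each scan takes out most of a change shared by all genes. Neither explanation would therefore give these calls by itself, and these comparisons do not bear on the centred differences. A smaller shared loss beside other differences stays possible. Debris or missing spots at 1 spot position would end the calls with that position left out, and 6 of 6 kept theirs whichever of the 3 was left out, while 0 of their 108 spot readings were outlying. Knockdown of ABCC4, the presence of a hairpin, another difference between the 2 cultures and a difference between the 2 arrays cannot be told apart. There was 1 RNA sample per group, and the labels name no control hairpin. Lower TAP1 and TAP2 in shMRP4 cells may thus be a property of this pair of cultures or arrays, and a second culture of each line would test it.

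TAP1 and TAP2 lie within 1 Mb of each other, as do ABCA5 and ABCA6, with differences of −2.21 and −1.34 for the TAP genes and of −0.55, which is under 2-fold, and −2.47 for ABCA5 and ABCA6. One hypothesis was that genes this close together differed by like amounts. Over the 5 such pairs the mean gap between neighbours was 0.96, against a median of 0.93 after 100000 shufflings (one-sided permutation p = 0.54), so these pairs could not decide it. The other pairs were ABCA4 and ABCD3, ABCB8 and ABCF2, and ABCC5 and ABCF3, where the values were 1.03 and 0.10.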
